A study of Rattus norvegicus with 63 samples.

How the data were processed

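The values analysed were those of 63 Affymetrix Rat Neurobiology U34 arrays. The deposited values are signal intensities per probe set on a linear scale, made with MAS5, per the submitters' processing notes, with the version, scaling target and detection calls not given in the sources used here. Per the labels' protocols, total RNA was checked on a Bioanalyzer, and biotinylated cRNA was made from 1 to 5 µg of it by in vitro transcription. The 2% trimmed mean of the deposited intensity over all probe sets lay between 250.8 and 251.3 on all arrays, so that the arrays had been scaled to each other before deposit. No array had values identical to another's, and the highest correlation between arrays was 0.986. There are no counts or depths for arrays.

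The table held 1322 probe sets. The 59 control probe sets were left out of all tests, and the 9 bacterial spike-in and 6 antisense rat controls among them served as measures of the array. Of the 1263 others, 1137 had 1 gene symbol, 8 had several and 118 had none in the platform annotation. Of these, 1132 were found by Entrez identifier in a RefSeq table, which changed 0 symbols, and the named ones stand for 720 genes. No gene was named from a probe set with several symbols. Every per-sample column was used.

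Each array was rescaled to a 2% trimmed mean of 500 over the non-control probe sets, values under a floor of 32 were set to it, and log2 was taken. A probe set was tested where its mean log2 signal over all arrays of the region, whatever the access, was at least that of a signal of 100, and in fits of all regions where this held for at least 1 region. For each region limma 3.58.1 in R 4.3.3 fitted the 3 access groups (lmFit, eBayes with an intensity trend), with Benjamini-Hochberg adjustment over the probe sets of each contrast and a threshold of 0.05. The mean over 6 regions, the region comparisons (also at least 2-fold) and the difference of the lateral hypothalamus from the other 5 regions came from 1 fit of all 63 arrays in 18 groups. Fold changes are between means of log2 signal, and MAS5 signal near background understates them. Gene lists were tested by camera with a preset correlation of 0.01 over lists with at least 4 genes tested, with 1 probe set per gene, the one with the highest mean, and again with an estimated correlation and with fry.

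The design, the 21 gene lists, the region markers, the alternatives and the rule for named genes were fixed before the data were examined. The rule named, among probe sets past the threshold, those with the largest rises and falls, 12 of each for long against no access in the lateral hypothalamus, 8 for long against short, 5 for short against no access, for the mean of 6 regions and for the difference between regions, and 4 for every other contrast and for the rise of each region. A gene with several probe sets was named once, by the one with the smallest p, with the others given where they disagree. Where fewer than 4 passed, the 4 smallest p were named as not passing. Up to 4 members with the smallest p were added for each list that was called and for each list of long against no access in the lateral hypothalamus. Th and Slc6a3 in the ventral tegmental area, Penk and Drd2 in the nucleus accumbens, and Hcrt, Pmch and Cartpt in the lateral hypothalamus were always named where the array has them. The 21 lists cover hypothalamic neuropeptides, glutamate, GABA, monoamine, acetylcholine and peptide receptor genes, activity-induced genes, synaptic vesicle, cytoskeletal and adhesion genes, 2 signalling groups, 2 groups of ion channels, neurotrophic and stress genes, and markers of oligodendrocytes, astrocytes, microglia, vessels and choroid plexus.

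Alternatives were the values as deposited, quantile normalization, no floor, no filter or a mean of 200, no intensity trend, array weights, no cross-hybridising probe sets (565 have such a suffix), a replicate block, only the groups compared, all arrays in 1 fit, adjustment over 18 contrasts, a 3-fold threshold, and each array left out in turn. Single measures of the arrays were compared by exact permutation tests. The fits were tested on simulated data with the real means and spreads and 200 changed probe sets. For long against no access with 4 arrays per group, 62.6% of 99 probe sets changed by 0.5 and 96.7% of 92 changed by 1 (log2) were recovered in the lateral hypothalamus, 65.0% of 97 and 91.7% of 96 in the nucleus accumbens and 29.6% and 72.4% of 98 each in the amygdala. With 3 per group the shares were 58.6% of 99 and 94.8% of 96 in the septum, 57.7% of 97 and 94.7% of 94 in the ventral tegmental area, and 4.04% of 99 and 39.6% of 96 in the medial prefrontal cortex. These shares hold for 200 changed probe sets. Where few change, the adjustment is stricter and a smaller share would be recovered, which was not simulated. No array date or hybridisation batch was used here.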

Results

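Gene expression was measured in 6 brain regions of rats that had 0, 1 or 6 h of daily access to intravenous cocaine at 0.25 mg per injection. The groups are called no access, short access and long access, and the labels give 8 rats for each. Total RNA of each dissected region was hybridised to a rat neurobiology oligonucleotide array with 1263 probe sets beside its controls. There were 63 arrays, with 4 per access group in the lateral hypothalamus, nucleus accumbens and amygdala and 3 per group in the septum, ventral tegmental area and medial prefrontal cortex. Nothing in the labels states whether RNA of several rats was pooled on an array, so p measures the spread between these arrays. The number of arrays limits the precision. The median signal of an array lay between 56.7 and 79.7, and 17.3% to 25.1% of its probe sets were at the floor.

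Each region was first set against the mean of the other 5, to ask whether the arrays carried the transcripts of the region named. Oxytocin (Oxt) in the lateral hypothalamus was higher by 6.59 ± 0.24 (log2, SE) than in the mean of the other 5 regions, vasopressin (Avp) by 5.10 ± 0.20, galanin (Gal) by 4.35 ± 0.12 and Sncg by 2.21. In the ventral tegmental area tyrosine hydroxylase (Th), which makes the precursor of dopamine, was higher by 6.70 ± 0.20 and the dopamine transporter (Slc6a3) by 6.53 ± 0.13. The vesicular monoamine transporter (Slc18a2) was higher there by 5.50 ± 0.09 and Ddc by 3.99 ± 0.10. The dopamine receptors Drd1 and Drd2 and the adenosine receptor Adora2a were higher in the nucleus accumbens by 3.65 ± 0.10, 3.43 ± 0.22 and 3.24 ± 0.12, and Rarb by 3.20 ± 0.25. Cholecystokinin (Cck) was higher in the medial prefrontal cortex by 3.37 ± 0.15, with Adra1d, Itpka and Stx1a at 3.23, 2.65 and 2.53. The amygdala was led by Nptxr at 2.81, Itpka at 2.12, Avp at 2.07 and Hrk at 2.02, and the septum by Igfbp2 at 2.46, Sod3 at 2.41, Enpp2 at 2.28 and Tspo at 2.18. At least 2-fold higher at an adjusted p under 0.05 (limma) were 27 of 858 probe sets in the lateral hypothalamus, 84 in the nucleus accumbens, 32 in the amygdala, 42 in the septum, 69 in the ventral tegmental area and 60 in the medial prefrontal cortex. Without probe sets that can cross-hybridise the counts were 16, 41, 14, 25, 36 and 31, and at least 3-fold higher were 5, 35, 11, 12, 31 and 21. Of the region markers fixed in advance and tested, 6 of 6 were higher in the lateral hypothalamus, 6 of 8 in the nucleus accumbens, 6 of 8 in the amygdala, where 1 was lower, 9 of 9 in the ventral tegmental area and 8 of 9 in the medial prefrontal cortex. In the septum 1 of 4 was higher and 2 were lower, so these markers did not set that region apart. Among the hypothalamic markers Nnat, Hcrtr2 and Sst were higher by only 0.67, 0.70 and 0.47. The hypothalamic peptides Hcrt, Pmch and Cartpt were not analysed here. No other part of the hypothalamus was sampled, so these markers do not tell its lateral part from the rest.

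The first question was which genes differed in the lateral hypothalamus between rats with long access and rats without cocaine. Nlgn3, a postsynaptic adhesion protein, was 3.87-fold higher with long access, from a log2 signal of 6.01 ± 0.74 to 7.97 ± 0.29 (SD, n = 4 arrays). Ctxn1 and the adrenergic receptor Adra2a were both 3.36-fold higher, the heparan sulphate proteoglycan Sdc3 3.01-fold and Atp1b2, a sodium pump subunit, 2.90-fold. Also higher were the potassium channel Kcnc4 (2.39-fold), the thyroid hormone receptor Thra (2.31-fold), Map1a (2.30-fold), the NMDA receptor subunit Grin2d (2.27-fold), the oligodendrocyte transcription factor Sox10 (2.20-fold), synapsin 1 (Syn1, 2.07-fold) and Syt11 (1.97-fold). Cck was 4.48-fold lower, from 8.54 ± 0.19 to 6.38 ± 0.65, followed by Camk2d (2.43-fold), Igfbp2 (2.38-fold), the G protein subunit Gnb1 (2.38-fold) and the calmodulin-binding Pcp4 (2.20-fold). Gria3, S100b, C4b, Slc2a5, Adora2b, Vim and Gria1 were lower by factors between 2.05 and 1.74. In all, limma called 213 of 718 probe sets, 96 higher and 117 lower, at an adjusted p under 0.05. The adjusted p of the genes named ranged from 8.69e-07 for Ctxn1 and Gnb1 to 0.0372 for Igfbp2. Thra, Gria1, Gria3, Camk2d, Igfbp2 and S100b had other probe sets that did not pass. Among these, probe sets of Thra (-0.08), Gria1 (0.09) and Camk2d (0.07) went the other way. Adra2a lay near the floor (log2 of 5) with no access, at 5.69, so its fold is less certain. The same holds for Nlgn3, with no access arrays at 5.28, 5.82 and 5.91, and for Cck, with long access array 3 at 5.55. With a threshold of 1.5-fold as well 91 were called, and without probe sets that can cross-hybridise 124 were called. Adjusted over all 18 contrasts of access within regions the count was 120, and in 1 fit of all 63 arrays it was 116.

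The no access arrays of the lateral hypothalamus stood apart from the other arrays of that region in their control probe sets. The 6 antisense control probe sets had a mean log2 signal of 7.03 ± 0.22 with no access, 5.59 ± 0.18 with short access and 5.54 ± 0.14 with long access (SD, n = 4). The 9 bacterial spike-in controls stood at 10.96 ± 0.13, 10.52 ± 0.26 and 10.30 ± 0.12. For each of these controls, no access against either cocaine group gave p = 0.0286 by a two-sided exact permutation test, the smallest that 4 against 4 can give, and 0.30 after adjustment over 72 comparisons. Over 858 probe sets, all 4 no access arrays correlated best with the mean profile of the ventral tegmental area among the other 5 regions, and all 8 short and long access arrays with that of the septum. Across the 213 called probe sets, the difference of long access from no access correlated with the level of the ventral tegmental area minus that of the lateral hypothalamus at r = -0.648. The corresponding r was 0.281 for the nucleus accumbens, 0.0185 for the amygdala, 0.288 for the septum and -0.00021 for the medial prefrontal cortex. With a profile of the ventral tegmental area made without any hypothalamic array r was -0.529 (95% bootstrap interval -0.67 to -0.37), across probe sets, which are not independent replicates. Over all 718 probe sets tested r was -0.404 for long and -0.342 for short against no access, and over all those tested in the other 5 regions the largest of 75 such correlations had a size of 0.244. Oxt was at 13.16 ± 0.09 in the no access arrays and at 13.10 ± 0.08 in the long access arrays. With the spike-in level as a covariate, 60 probe sets were called for long access, 56 of them among the 213, and 66 for short access, 60 of them among the 161. Of the 213 differences 206 kept their direction, and over the 157 no longer called the median difference was 0.945 times and the median standard error 1.99 times that without the covariate. Nlgn3 went from 1.95 ± 0.32 to 2.00 ± 0.65 (log2, SE) and Vim from -0.84 ± 0.16 to -0.82 ± 0.32, while Adra2a went from 1.75 ± 0.22 to 1.01 ± 0.37 and Sdc3 from 1.59 ± 0.43 to 0.63 ± 0.83. For short access all 161 kept their direction, at 0.972 times the difference and 1.53 times the standard error over the 101 no longer called. The 3' to 5' ratios of actin and Gapdh, signs of RNA degradation, differed by -0.05 (p = 0.657) and -0.08 (p = 0.143) between long and no access and by 0.11 (p = 0.343) and -0.01 (p = 0.886) between short and no access, by the same exact test.

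**Figure D1:**
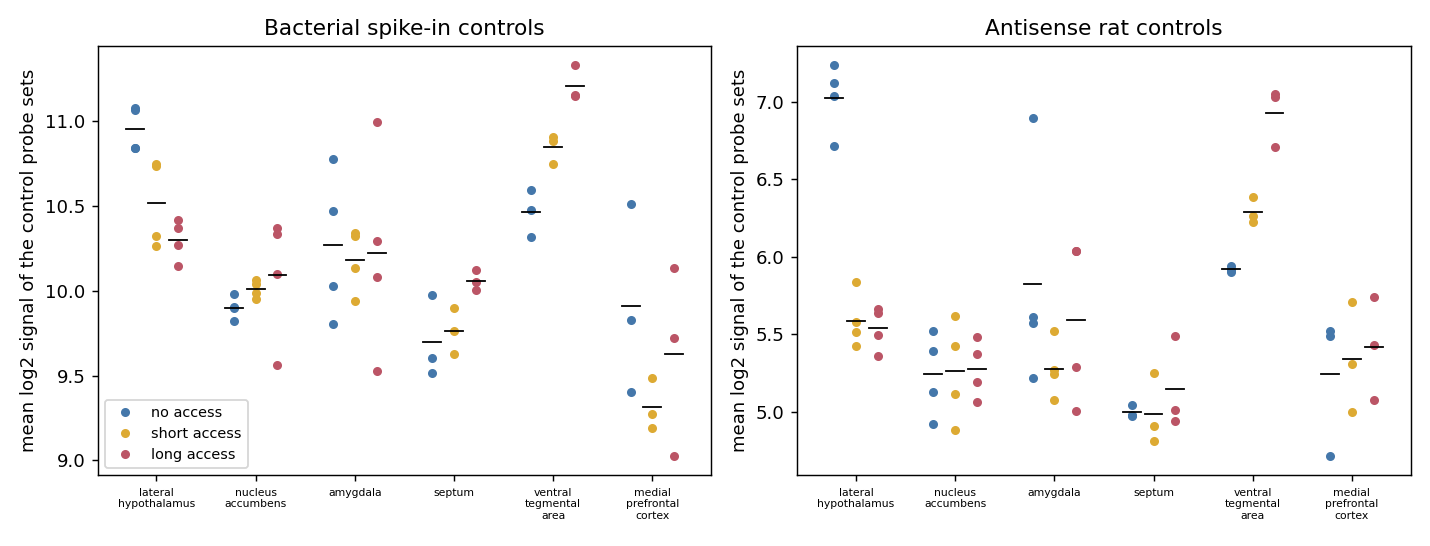
Mean log2 signal of the spike-in controls (left) and of the antisense rat controls (right) on every array, by region, with 1 point per array, colours for the access groups and black bars for group means. In the lateral hypothalamus the 4 no access arrays lie between 6.71 and 7.23 for the antisense controls, above all 8 other arrays of that region, and in the ventral tegmental area the long access arrays lie highest.

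The genes that differed in the lateral hypothalamus were then grouped by 21 lists, and none was called for long against no access by camera with a preset correlation (lowest adjusted p 0.0634, with 3 lists at an unadjusted p under 0.05). With an estimated correlation 0 were called, by fry 7, with no filter on dim probe sets 2, with array weights 1, and by camera 1 without no access array 4 or long access array 1 or 4. The no access arrays that stood apart in their controls enter every count. Of 22 genes of calcium, cyclic AMP and protein kinase C signalling, 7 fell and 0 rose, among them Gnb1, Pcp4, Prkcb (log2 difference -0.52) and Calm2 (-0.35), and adjusted over the list alone 8 fell. Of 22 synaptic vesicle genes 6 rose and 3 fell, with Syn1 at 1.05, Syt11 at 0.98, Syt3 at 0.91 and Rab3a at 0.88. Of 19 glutamate receptor genes 4 rose and 2 fell, Grin2d (1.18) and Grin2c (0.51) among the first and Grik4 (-0.75) among the second. Both the vesicular GABA transporter Slc32a1 (0.69) and Gabbr2 (0.48) rose among 14 GABA genes. Of 18 monoamine genes Adra2a and Th (0.52) rose while Maoa (-0.34) and Maob (-0.36) fell. The immediate early gene Egr1 fell by 0.72 and Crem fell by 0.46 among 11 activity-induced genes. Among 11 cytoskeletal genes Map1a and Mapt (0.44) rose and the neurofilaments Nefh (-0.41) and Nefm (-0.37) fell. Of 14 adhesion genes 3 rose, led by Nlgn3 and Nptxr (0.44), and Nrp1 fell (-0.46).

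Of 23 potassium channel genes 4 rose and 3 fell, including Kcnc4, Kcnj10 (0.91) and Kcnc2 (-0.61). Among 16 sodium and calcium channel genes Scn2a rose (0.57) and Scn1a fell (-0.62). Of 23 neurotrophic genes 4 rose, among them Vgf (0.74) and Fgfr1 (0.71), and 4 fell, among them Cntf (-0.62). Of 10 kinase signalling genes 3 rose, Mapk14 (0.45) among them, and 2 fell, Fyn (-0.49) among them, and of 18 stress and apoptosis genes 3 rose and 5 fell, Bcl2l1 at 0.87 and Sod1 at -0.42. Cck fell as the 1 neuropeptide of 11 that passed, a list whose median (0.01) and mean (-0.14) differ in sign, while Gal (0.38) and Pdyn (0.31) did not. Of 8 peptide receptor genes Hcrtr1 fell (-0.53), and of 8 acetylcholine genes 0 passed. The markers of other cell types moved apart from each other: of 6 oligodendrocyte markers Sox10 and Mag (0.55) rose and Mog, Mbp and Tf fell, and of 9 astrocyte markers Kcnj10 rose while Apoe (-0.61), Vim (-0.84) and Glul (-0.21) fell. Among 5 microglial and immune markers B2m (-0.67) and Il18 (-0.59) fell, the glucose transporter Slc2a1 (-0.71) fell among 4 vessel markers, and 0 of 4 choroid plexus markers passed. Adjusted over each list alone, the counts were otherwise the same save for 3 cytoskeletal genes that rose, 6 stress genes that fell, 0 peptide receptor genes and 0 sodium or calcium channel genes that rose. Prkcb, Grik4, Gabbr2, Egr1, Mapt, Kcnc2, Mapk14, Sod1, Mag, Mog, Tf and Glul had other probe sets that did not pass. Those of Prkcb and Egr1 went the other way, as did 1 each of Mapk14, Tf and Mag, whose others were at -0.05 and 0.14.

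Short access was set against no access in the same region to ask how much of this was seen with 1 h of cocaine a day. Ctxn1 was 3.45-fold higher, Adra2a 3.10-fold, Sox10 2.29-fold, Vegfb 2.17-fold and Grin2d 2.02-fold. Igfbp2 was 3.13-fold lower, Camk2d 2.67-fold, Pik3r1 2.35-fold, Synpo 2.14-fold and Gnb1 1.99-fold. Igfbp2 (-0.40) and Camk2d (-0.28) each had another probe set that did not pass, and Adra2a with no access lay near the floor as above. In all 161 of 718 probe sets were called by limma, 74 higher and 87 lower, and 0 gene lists by camera, with 4 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0884 for astrocyte markers. The count of probe sets was 66 with a threshold of 1.5-fold as well, 87 without those that can cross-hybridise, 87 when adjusted over 18 contrasts and 75 in 1 fit of all 63 arrays. By fry 5 lists were called, with no filter 4, and by camera 1 without no access array 3 or short access array 4. Between the effects of long and short access, 50 probe sets were called higher in both and 56 lower in both, where independent lists would share 9.89 and 14.2, and 1 went opposite ways. Without probe sets that can cross-hybridise 58 were shared in all. Both comparisons use the no access arrays described above. Across probe sets their differences correlated at 0.717 with a covariance of 0.118, and simulated unchanged groups against shared controls gave 0.505 and 0.0199. With the 4 controls split into pairs, 1 pair for each comparison, r averaged 0.494 and the covariance 0.0936 over 6 splits. The simulated values are for shared controls and are no reference for these, for which unchanged groups were not simulated. Both pairs are no access arrays, so a shift of that whole group stays in both comparisons.

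Long access was set against short access to find what differed between rats that both took cocaine, a comparison whose difference does not use the no access arrays. The potassium channel Kcnj10 was 2.51-fold higher with long access, from 7.77 ± 0.53 to 9.10 ± 0.04 (SD, n = 4). Nlgn3 was 2.39-fold higher, Syt11 2.15-fold, Atp1b2 2.13-fold, Nptxr 1.89-fold, Kcnc4 1.81-fold, Kcna6 1.80-fold and the sodium channel Scn8a 1.77-fold. Cck was 2.67-fold lower, C4b 2.56-fold, the calcium channel Cacna1a 2.53-fold, Gria1 1.78-fold, Hrk 1.71-fold, Mag 1.51-fold, Cox6c 1.45-fold and Smarcb1 1.42-fold. The count was 64 of 718 probe sets by limma, 36 higher and 28 lower. Nptxr, Hrk, Cacna1a, Gria1, Mag and Smarcb1 had other probe sets that did not pass, and those of Nptxr and 1 of Mag went the other way. The synaptic vesicle list shifted upwards (camera, adjusted p = 0.0379), with 5 of 22 genes higher, adjusted over the list alone 5 as well: Syt11, synaptophysin (Syp, 0.49), Syt3 (0.75), Rab3a (0.59) and Sncb (0.64). With an estimated correlation its adjusted p was 0.156. The antisense controls of these groups differed by -0.05 (p = 0.714, exact permutation test) the spike-in controls by -0.22 (p = 0.257) and the actin 3' to 5' ratio by -0.16 (p = 0.0571). The count was 29 with the actin 3' to 5' ratio as a covariate, 15 in 1 fit of all arrays and 38 when adjusted over 18 contrasts, and 37, 31, 41, 40 and 40 without short access array 1, 2 or 3 or long access array 1 or 2. The vesicle list was not called without short access array 3 or 4 or long access array 1 or 2. Nor was it called with no intensity trend (camera, adjusted p = 0.0633) or with a replicate block (0.0563). There were 3 lists called without short access array 2 or by fry, and 2 with no filter or without cross-hybridising probe sets.

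**Figure D2:**
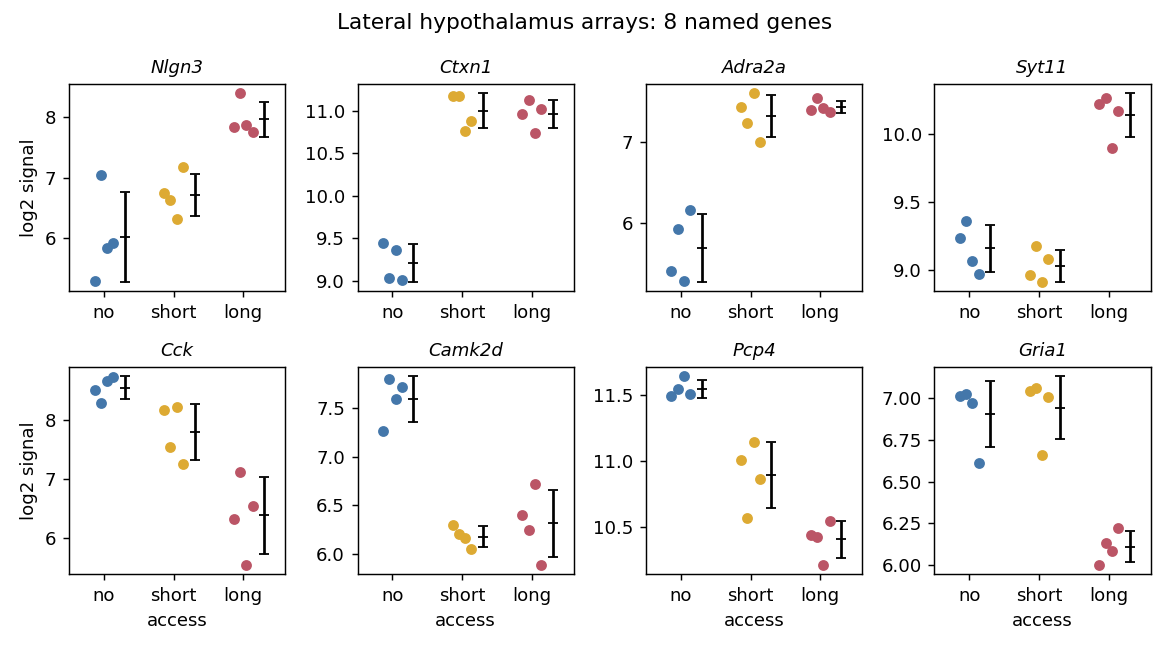
Log2 signal of 8 named genes on the 12 arrays of the lateral hypothalamus, with 1 point per array and the mean ± SD of each access group beside it. Nlgn3 averages 6.01, 6.71 and 7.97 with no, short and long access, and Cck averages 8.54, 7.80 and 6.38.

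Whether the hypothalamic differences stood apart from those elsewhere was tested directly, as the difference in the lateral hypothalamus minus the mean difference in the other 5 regions. For long against no access, Nlgn3 exceeded the other regions by 2.19 ± 0.44 (log2, SE), Adra2a by 1.90 ± 0.33, Ctxn1 by 1.83 ± 0.22 and Igf2 by 1.49 ± 0.41. Pdgfb did so by 1.57 ± 0.43, but all 4 no access arrays of the lateral hypothalamus were at the floor, so that its difference there has only a bound, and Igf2 lay near the floor there, at 5.26 and 6.09, as did Adra2a with no access and Slc1a3 with long access (5.80). Cck lay below them by -1.83 ± 0.34, Camk2d by -1.54, Slc1a3 by -1.52, Gnb1 by -1.25 and Pcp4 by -1.22. Single hypothalamic arrays of Nlgn3 with no access (5.28) and of Cck with long access (5.55) also lay near the floor. The difference was called for 110 of 858 probe sets, 52 above and 58 below, and for 1, Syp at 0.47 ± 0.09 (adjusted p = 0.00828), for long against short access. Next in the latter, without passing, were Slc18a2 (0.89), Ptk2b (1.10) and Fyn (-0.48), and 72 had an unadjusted p under 0.05. The first count rests on the no access arrays described above, and it was 71 without the fourth of them. It was 215 with array weights and 69 without probe sets that can cross-hybridise. The count for long against short access was 54 with array weights, 14 without the medial prefrontal cortex arrays, 7 with a filter at a mean of 200, 6 with quantile normalization, and 2 with no filter or no intensity trend. With single arrays left out it was 10 without medial prefrontal cortex short access array 3, 8 without its no access array 3, 7 without lateral hypothalamus no access array 4 and 5 without ventral tegmental area long access array 2. It was 4 without amygdala short access array 3 or hypothalamic long access array 2, and 3 without amygdala short access array 1, 2 or 4, hypothalamic no access array 3 or short access array 4, or septum long access array 1. It was 2 without nucleus accumbens long access array 4, hypothalamic no access array 1 or 2, short access array 3 or long access array 1, 3 or 4, septum short access array 1 or septum long access array 3.

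In the nucleus accumbens, the main target of the ventral tegmental dopamine neurons, no gene passed. Smallest in p for long against no access were Itpr1 (-0.61 ± 0.12, log2, SE), the serotonin transporter Slc6a4 (1.49 ± 0.35), Sox10 (0.39 ± 0.10) and Ppp1r9a (-0.62 ± 0.15), with adjusted p of 0.107 and, for the last 3, 0.132. Mt2A (-0.59), Gnb1 (-0.96), Kcnf1 (-0.52) and Gfra2 (0.64) led short against no access at an adjusted p of 0.118. Gnb1 led long against short access at 1.13 ± 0.21 (adjusted p = 0.0594), then Cx3cl1 (-0.53), Mt2A (0.42) and Ncam1 (-0.42) at 0.361. For long against no access enkephalin (Penk) differed by 0.23 ± 0.12 and Drd2 by -0.12 ± 0.16, and neither passed in any contrast. By limma 0 of 738 probe sets were called in each contrast, and 119, 75 and 71 had an unadjusted p under 0.05 for long against no, short against no and long against short access. These were 16.1%, 10.2% and 9.62%, more than unchanged probe sets give on average, so the lack of calls does not show that nothing differed. No gene list was called by camera for long against no access, with 1 at an unadjusted p under 0.05 and a lowest adjusted p of 0.301. Itpr1, Cx3cl1 and, for long against short access, Gnb1 had other probe sets that went the other way. The actin 3' to 5' ratio was higher than with no access by 0.16 with long and by 0.08 with short access (p = 0.0286 each, exact permutation test, and 0.30 after adjustment). The counts were 1 for short against no access without long access array 4, 1 for long against short access without short access array 2, and 1 list without long access array 3. Other settings made calls too: short against no access gave 9 with array weights, 7 when adjusted over 18 contrasts, 2 with no filter or in 1 fit of all arrays and 1 with only the groups compared. Long against no access gave 7 when adjusted over 18 contrasts, and long against short access 2 with no filter and 1 with either of adjustment over 18 contrasts or 1 fit of all arrays. Adjustment over 18 contrasts takes in the many small p of the lateral hypothalamus, which eases the threshold for other regions.

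In the amygdala, insulin-like growth factor 2 (Igf2) was lower with long access than with no access, at 10.05 ± 0.15 against 11.55 ± 0.47 (SD, n = 4), a 2.81-fold difference with an adjusted p of 0.00818 by limma. Its other 2 probe sets were at -0.07 and -0.35 and did not pass. Vim (-1.01 ± 0.22), C4b (-0.82 ± 0.23) and Igfbp2, which was 2-fold lower, followed and did not pass. Markers of choroid plexus and ependyma, the lining and secretory tissue of the ventricles, shifted downwards as a list (camera, adjusted p = 0.00777, and adjusted p = 0.110 with an estimated correlation). Of its 4 genes Igf2 fell, Igfbp2 also passed when adjusted over the list alone, and Enpp2 (-0.16) and Htr2c (0.45) did not. In the other contrasts 0 of 732 probe sets were called by limma, with 32 and 30 at an unadjusted p under 0.05. Igf2 (-0.79), Bmyc (0.60), Stat3 (-0.77) and Atp2b1 (-0.46) had the smallest p for short against no access, and Slc2a3 (0.75), Igf2 (-0.71), P2rx2 (0.49) and Sst (-0.40) for long against short access. The Gapdh 3' to 5' ratio differed by -0.32 between long and no access (p = 0.0571, exact permutation test). The Igf2 call ended without no access array 4 (limma, adjusted p = 0.0528), with no filter on dim probe sets (0.0995) and with a replicate block (0.0659). Its probe set is among those that can cross-hybridise, without which 0 were called. There were 2 calls without no access array 2 or short access array 2, in 1 fit of all arrays and when adjusted over 18 contrasts. The choroid plexus list was not called without no access array 2, with no filter (camera, adjusted p = 0.0583) or with a replicate block (0.0744). It had under 4 genes to test without cross-hybridising probe sets. There were 2 lists called with no filter or without no access array 3 or long access array 1, and 3 with array weights or without long access array 2.

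In the septum 17 of 736 probe sets were called for long against no access. Hspb2 was higher by 0.93 ± 0.21 (log2, SE), Kcnj10 by 0.76 ± 0.10, the growth factor receptor Fgfr1 by 0.72 ± 0.07 and 1 Gnb1 probe set by 0.46 ± 0.08, while Igf2 (-1.14 ± 0.17), Nptxr (-0.87 ± 0.09), Mag (-0.68 ± 0.09) and the GABA receptor Gabbr1 (-0.63 ± 0.07) were lower. With short access Stx7 (0.88), Nefh (0.41) and Fgfr1 (0.31) were higher and Nptxr (-1.14), another Gnb1 probe set (-0.92), Hes1 (-0.79) and Smad7 (-0.72) lower among 14 called. Between long and short access 15 were called, led by Sst (0.50), Gnb1 (0.50), Ptk2b (0.45), Hspb1 (0.42), Igf2 (-0.88), Stx7 (-0.72), Mag (-0.41) and Nefm (-0.39). The list of choroid plexus and ependyma markers shifted downwards with long access (camera, adjusted p = 0.00291, and adjusted p = 0.231 with an estimated correlation), with 1 of 4 genes passing, Igfbp2 (-0.33), and 3 adjusted over the list alone. For long against no access Kcnj10, Fgfr1, Gnb1, Igf2, Mag and Gabbr1 had other probe sets that went the other way. Spike-in controls were higher with long access by 0.36 than with none and by 0.30 than with short access, and with short access the 3' to 5' ratios of actin and Gapdh were each 0.16 above those with none and that of actin differed by -0.15 between long and short access (p = 0.10 for each, 0.30 after adjustment, exact permutation test, the smallest that 3 against 3 can give). Without probe sets that can cross-hybridise that list had a mean difference of 0.08 (adjusted p = 0.703), and 5 and 3 probe sets were called for long against no and long against short access. In 1 fit of all 63 arrays 0 probe sets were called in any of these contrasts. With array weights 27 and 31 were called for long and short against no access, and with no intensity trend 8 and 5 for short against no and long against short access, the latter giving 9 with only the groups compared. By fry 5 lists were called, and with no filter 2. Without 1 array, long against no access gave 11, 10 and 9 (no access arrays 1, 2 and 3) and 9 and 10 (long access arrays 2 and 3), and short against no access gave 8 and 7 (no access arrays 1 and 2) and 7 and 8 (short access arrays 1 and 3). Long against short access gave 0, 1 and 6 without short access arrays 1, 2 and 3 and 0, 0 and 2 without long access arrays 1, 2 and 3.

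In the ventral tegmental area, where the dopamine neurons lie, Th differed by 0.15 ± 0.07 and Slc6a3 by 0.19 ± 0.09 (log2, SE) between long and no access, with adjusted p of 0.320 and 0.351 by limma. The adenosine receptor Adora1 was higher with long access by 1.01 ± 0.23, the astrocytic S100b by 0.89 ± 0.15, Cspg5 by 0.69 ± 0.12 and Igf2 by 0.59 ± 0.07. Igfbp5 (-0.63 ± 0.13), Gmfb (-0.53 ± 0.11), Vdac1 (-0.49 ± 0.10) and Map2 (-0.49 ± 0.11) were lower. In this contrast 21 of 722 probe sets were called, 66.7% of them higher, or 55.0% of 20 with quantile normalization. With short access 6 were called, among them Mag (0.61), Nefm (0.29), Gnb1 (-0.96), Sod1 (-0.57) and Hspb1 (-0.57), and 19 between long and short access, led by Pik3r1 (0.96), Gnb1 (0.82), Hspb1 (0.69), S100b (0.68), Igfbp5 (-0.61), Vdac1 (-0.47), Nefl (-0.38) and Snap25 (-0.27). No gene list was called by camera for long against no access (lowest adjusted p 0.950, and 0 at an unadjusted p under 0.05). Igf2, Map2, Sod1, Hspb1 and, for long against short access, S100b had other probe sets that went the other way. The spike-in controls were higher with more access here, from 10.46 ± 0.14 through 10.85 ± 0.09 to 11.21 ± 0.10 (SD, n = 3), and the antisense controls from 5.92 ± 0.02 through 6.29 ± 0.08 to 6.93 ± 0.19, each pair of groups at the smallest possible p of 0.10 (exact permutation test). The actin 3' to 5' ratio was higher by 0.21 with long and 0.27 with short access and that of Gapdh by 0.19 with long access, also at p = 0.10 by the exact test. With the spike-in level as a covariate 0 probe sets were called in each contrast. Of the 21 differences between long and no access 18 kept their direction, and the median difference was 0.859 times and the median standard error 3.46 times that without the covariate. S100b was then at 1.78 ± 0.46, Vdac1 at -1.03 ± 0.30, Igfbp5 at -0.50 ± 0.46, Map2 at -0.42 ± 0.39, Igf2 at 0.35 ± 0.25 and Cspg5 at 0.25 ± 0.40, while Adora1 (-0.25 ± 0.72) and Gmfb (0.13 ± 0.34) lay on the other side of 0. All 6 and 19 differences of the other contrasts kept their direction, with median standard errors 1.99 and 1.89 times as large. In 1 fit of all arrays 0 were called, without probe sets that can cross-hybridise 5, 2 and 1, and with no intensity trend 8, 3 and 7. With no filter 10 and 1 were called for long and short against no access, and with array weights 38 for long against no access. Without 1 array, long against no access gave 8 and 10 (no access arrays 1 and 2) and 12 and 13 (long access arrays 2 and 3), short against no access gave 3 (no access array 2), 2 and 3 (short access arrays 2 and 3), and long against short access gave 8 (short access array 3), 12 and 10 (long access arrays 2 and 3).

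In the medial prefrontal cortex 0 of 680 probe sets were called by limma in any contrast, and 4, 2 and 2 had an unadjusted p under 0.05. These were 0.588%, 0.294% and 0.294%, far fewer than unchanged probe sets give on average where p is well calibrated. The median standard error was 0.297, against 0.151 in the lateral hypothalamus. The spread may thus be overstated here, and 0 calls do not show that nothing changed. Gabbr1 (-0.96 ± 0.33), Nptxr (0.51 ± 0.19), Tgfb3 (-0.57 ± 0.24) and Foxd3 (0.68 ± 0.30) had the smallest p for long against no access. Tnfrsf1a (2.30-fold higher), Gnb1 (log2 -0.68), Hnrnpu (-0.53) and Gsk3b (-0.53) did for short against no access, and Adora2b (-0.64), Scn1a (0.63), Syt4 (0.40) and Vim (-1.08) for long against short access. Astrocyte markers shifted downwards as a list with long access (camera, adjusted p = 0.0110, and adjusted p = 0.208 with an estimated correlation), though 0 of its 9 genes passed, adjusted over the list alone 0 as well. Nptxr and Gnb1 had other probe sets that went the other way. The actin 3' to 5' ratio spread widely within the groups here, with SDs of 1.03, 0.91 and 0.64 (log2, n = 3) against 0.17, 0.08 and 0.07 in the lateral hypothalamus. Without the 3 arrays numbered 3, whose ratios were the highest, the list was not called, nor was it without no access array 2 or 3 or long access array 2 or 3 alone. It was also not called with quantile normalization, no filter, array weights, no cross-hybridising probe sets or fry, with adjusted p between 0.102 and 0.585.

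Averaged over all 6 regions, the NMDA receptor subunit Grin2d was higher with long than with no access by 0.37 ± 0.06 (log2, SE), Fgfr1 by 0.33, Mapk14 by 0.30, Syt3 by 0.27 and Vgf by 0.21, and Cck (-0.63), Kcnj4 (-0.50), Adora2b (-0.37) and Kcnd2 (-0.32) were lower. This made 10 of 858 probe sets by limma. With short access 7 were called, among them the complement gene C3 (0.67), Kcnc1 (0.25), Capns1 (0.19), Gnb1 (-0.79 ± 0.09), Pik3r1 (-0.77) and Sod1 (-0.33). Long against short access gave 2, Gnb1 (0.67 ± 0.09) and C3 (-0.83 ± 0.16), and next Fgfr1 (0.28) and C4b (-0.47), which did not pass. The value of Gnb1 is that of 1 of its 5 probe sets, and the other 4 did not pass, at -0.28 to -0.23 for short against no access and 0.18 to 0.27 for long against short access. The other probe sets of Sod1 went the other way. The hypothalamic arrays enter these means, and regions of the same rats, which the labels do not tell apart, would make these p too small. With array weights the counts were 62, 33 and 13 for long against no, short against no and long against short access. For short against no access the count was 4 with no floor, 3 with quantile normalization and 2 without probe sets that can cross-hybridise, and for long against short access 1 with a filter at a mean of 200 and 0 without probe sets that can cross-hybridise. With single arrays left out, the count for long against no access was 3 without nucleus accumbens long access array 4, septum or ventral tegmental area long access array 3, or cortical no or long access array 2. It was 4 without nucleus accumbens long access array 2, amygdala no access array 3 or long access array 4, hypothalamic long access array 1, or septum no access array 1 or long access array 2. It was 5 without nucleus accumbens no access array 2 or 4, amygdala long access array 3, hypothalamic no access array 2 or 3 or long access array 2, septum long access array 1 or ventral tegmental area no access array 1, and 6 without hypothalamic no access array 4. For short against no access it was 20 without amygdala short access array 1, 15 and 12 without nucleus accumbens short access array 3 and long access array 1, 11 without cortical no access array 2 or 3 or short access array 1, and 3 without cortical no access array 1. For long against short access it was 6 without cortical long access array 1 and 4 without amygdala long access array 2, hypothalamic short access array 2, cortical short access array 1 or 2, or cortical long access array 2 or 3.

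**Figure D3:**
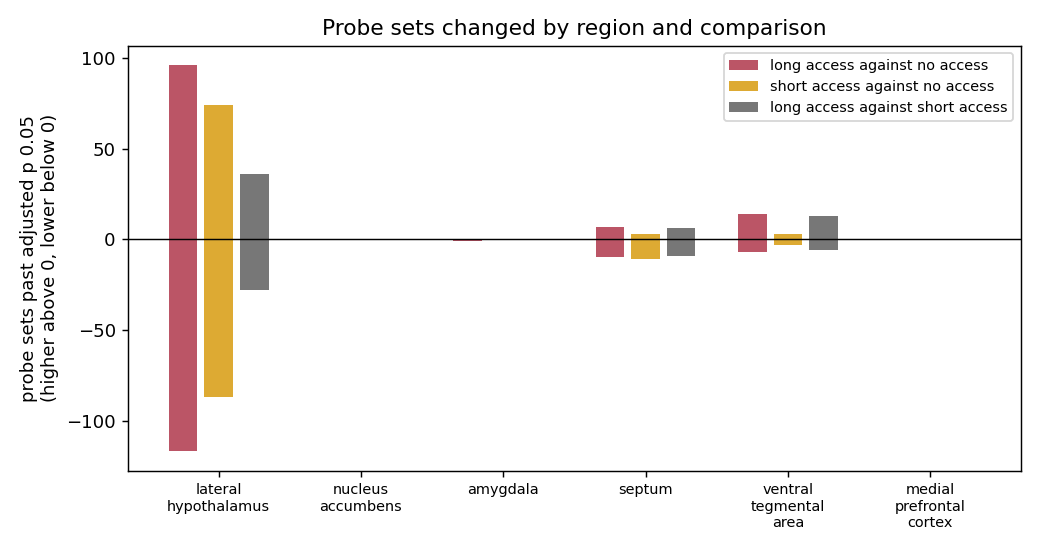
Number of probe sets past an adjusted p of 0.05 in each region and contrast of access groups, with higher ones drawn above 0 and lower ones below. The lateral hypothalamus has 213, 161 and 64 calls, and no other region has more than 21.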

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

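The tests of spike-in strength, of a batch shared with the ventral tegmental area, of ventral tegmental tissue by its own transcripts and of explanations for the Gnb1 pattern were chosen only after the results were seen. So were the antisense measure and the covariates.

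Between the lateral hypothalamus and the mean of the other 5 regions, the effect of long against no access differed for 110 probe sets, with Nlgn3 at 2.19, Adra2a at 1.90, Ctxn1 at 1.83, Pdgfb at 1.57, Igf2 at 1.49, Cck at -1.83, Camk2d at -1.54, Slc1a3 at -1.52, Gnb1 at -1.25 and Pcp4 at -1.22 on the log2 scale. For long against short access it differed for 1, Syp at 0.47. All 4 no access arrays of the lateral hypothalamus were at the floor for Pdgfb, whose difference there has only a bound, and Igf2, Adra2a and Slc1a3 lay near it in 1 or both groups. So did single arrays there of Nlgn3 with no access (5.28) and of Cck with long access (5.55). Outside the tested probe sets, the spike-in controls were higher on every long access array than on every no access array in the septum (by 0.36) and in the ventral tegmental area (by 0.75).

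The pattern of most weight is that the many differences from no access in the lateral hypothalamus lie along a profile of the ventral tegmental area and that the no access arrays stand apart in their controls. RNA degradation is argued against by 200 calls with the actin ratio as a covariate, 192 of them among the 213. Hybridisation strength alone would need a correlation below -0.3 with the ventral tegmental differences, where the spike-in controls move the opposite way. The correlation was 0.167 (95% bootstrap interval over probe sets 0.00922 to 0.309). This cannot decide the question, because noise pulls such a correlation towards 0. Over all probe sets tested there the ventral tegmental differences had a median size of 0.147 and a median standard error of 0.162. With the spike-in level as a covariate, which itself separates the hypothalamic no access arrays from the others, 56 of the 213 calls stay and 157 end. Of these 157, 150 kept their direction, at a median of 0.945 times the difference but 1.99 times the standard error (Slc2a5 from -0.91 ± 0.19 to -0.76 ± 0.38). Tissue like that of another region met the prediction written for it beforehand, a correlation beyond 0.5, at -0.648, but for ventral tegmental tissue itself 8 probe sets for its transcripts allow a median share of 5.26% (1.17% to 49.6%, lowest but one 2.47%, the summary used at first and replaced after both were seen), against a median of 31.8% needed over 13 probe sets. Neighbouring tissue that was not sampled therefore stays open, and so does a labelling or hybridisation batch shared with the ventral tegmental arrays, for which r was -0.529, in a region picked as the closest of 5. No batch was given for these arrays in the sources used here. A batch that set the no access arrays apart, a difference in dissection and an effect of cocaine therefore cannot be told apart for either comparison with no access. The differences between long and short access do not use those arrays, though the spread in their fit and the filter do. These differences also correlated with that profile, at -0.147 over 718 probe sets.

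In the amygdala Igf2 was lower with long access, and the values of Igfbp2 and Vim were lower too but did not pass. The choice among the 3 scalings tried did not make this difference, since the smallest Igf2 difference over them was -1.49. The arrays had been scaled to each other before deposit, which these settings do not test. A varying amount of choroid plexus, ependyma or meninges in the dissections may contribute: with group means removed the 3 genes varied together over 12 arrays with a mean pairwise r of 0.733. The pairs had r of 0.771, 0.747 and 0.680 (permutation p 0.019, 0.053 and 0.049, adjusted p 0.053 for each of 3, which does not pass) and rho of 0.692, 0.762 and 0.720 (permutation p 0.024, 0.053 and 0.03, adjusted p 0.045, 0.053 and 0.045), and r was 0.702, 0.588 and 0.633 without the 2 arrays farthest out. Of the choroid plexus genes, Enpp2 (-0.16) and Htr2c (0.45) did not fall with them, and an effect of access on these genes was not tested apart from the dissection.

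For Gnb1, 1 of 5 probe sets was lower on short access arrays by far more than the other 4 in the mean of the 5 regions other than the lateral hypothalamus. A change in Gnb1 mRNA is argued against as the whole of this, since in that mean its difference from no access was -0.78 and that of the other 4 probe sets -0.12, but a smaller change stays open, as 18 of their 20 values lay below 0. With short access 2 probe sets, this one and 1 other, were lower than with both other groups in all 6 regions, and the other 3 in 4 regions each, which an array or hybridisation batch shared by the short access arrays could also give. No batch was given in the sources used here, so a batch that followed access cannot be told apart from access. In the lateral hypothalamus all 5 were lower with either access group than with none, and in 3 regions (septum, ventral tegmental area and medial prefrontal cortex) all 5 were higher with long than with short access, with each past the threshold in the ventral tegmental area alone, so the argument covers short against no access in the other 5 regions.

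Of 213 groups of 4 arrays, 13 held an array far from the other 3, where chance gives 10.7. In the lateral hypothalamus these were Nlgn3 at 8.40 on long access array 2, S100b at 8.84 and Gria1 at 6.61 on no access arrays 1 and 4, Gria1 at 6.66 on short access array 3, Vegfb at 8.91 and Gnb1 at 10.10 on long access array 3, and Cox6c at 8.87 on no access array 4. In the nucleus accumbens they were Gnb1 at 8.54 on long access array 2, Kcnf1 at 8.16 on short access array 2, and Gfra2 at 7.15 on no access array 2 and at 7.78 on short access array 4. In the amygdala they were Stat3 at 9.37 and P2rx2 at 8.55 on long access array 3.

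Other splits of the arrays were counted for every result. In the lateral hypothalamus 1 of 35 splits gave as many calls in each contrast, the real one, with 213, 161 and 64 against at most 1, 2 and 0 in any other. That is the fewest this test can give for 1 contrast, and 18 contrasts were tried, so the splits alone do not exclude chance. Mixing 2 groups that differ also widens the spread within groups, which lowers the counts of the other splits. A batch that follows the groups is not tested by them. For the 1 call in the amygdala 1 of 35 splits reached it (0 in any other), the fewest this test can give. Chance is not excluded for it, since 18 contrasts were tried. Splits of the other 2 amygdala contrasts called up to 11 and 62 probe sets. Chance is not excluded for the synaptic vesicle list (9 of 35 splits gave 1 list or more, up to 3) or the choroid list in the amygdala (7 of 35, up to 1). Where the real count was 0, all 35 splits reach it, and other splits called up to 3 and 2 lists in the lateral hypothalamus for long and short access against none. In the nucleus accumbens they called up to 11, 3 and 5 probe sets and 1 list, and in the amygdala up to 11 and, for long against short access, 62 probe sets. What set the arrays of those splits apart was not tested. The 10 splits of 3 against 3 are too few to exclude chance. There the real split gave 17, 14 and 15 in the septum and 21, 6 and 19 in the ventral tegmental area, where 1 split reached each and any other gave 0. The 1 list in the septum was reached by 2 splits (up to 2 lists), the 1 list in the medial prefrontal cortex by 2 (up to 1), and counts of 0 by all 10. Of 100 drawn splits, 1 reached the mean over regions for long (10, highest other 9) and short (7, highest other 3) against no access and the hypothalamic difference for long against no access (110, highest other 98), with labels drawn separately in each region. That excludes chance only if arrays of different regions are independent, which the labels do not state. For the hypothalamic difference the draws remove the effects of all regions at once. They therefore do not test by themselves whether the hypothalamic effect departs from that of the other regions. For the 106 calls shared in the lateral hypothalamus 1 of 100 reached the count (highest other 0). This argues against chance for a difference among the 3 groups. It does not test whether long and short access effects are shared, since both contrasts use the no access arrays and the draws mix those too. For long against short access 5 reached the 2 calls of the mean (up to 8) and 10 the single hypothalamic one (up to 2), so chance is not excluded. For the region comparisons 1 of 100 reached 27, 84, 32, 42, 69 and 60, with at most 12, 14, 0, 7, 15 and 13 in another.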

How the results depend on the processing

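The spike-in and actin covariates, the cortical arrays left out and the 1.5-fold threshold were chosen after the data were seen. Of the alternatives, 1193 values for counts stayed within 1.5 times and 226 moved beyond it. For named genes 6747 values kept direction and side of the threshold, 607 no longer passed, 76 newly passed and 7 turned, and where no cause is given it was not tested. The reversed values were all of genes far from the threshold or under a covariate: Th with short access in the ventral tegmental area -0.036 with quantile normalization, Adora1 -0.25, Gmfb 0.13 and Slc6a3 0.091 there with the spike-in covariate, Slc6a3 (short against no access, from -0.0876 to 0.0977 without single arrays) 0.01 without no access array 1 and 0.0977 without short access array 2, and Drd2 0.0213 without nucleus accumbens long access array 3. The counts that moved are given as the main count and then the other. Quantile normalization moved mean of 6 regions short against no 7 to 3, the hypothalamic difference from the other 5 regions, long against short 1 to 6, medial prefrontal cortex long against no gene lists 1 to 0. No floor moved mean of 6 regions short against no 7 to 4. No filter on dim probe sets moved nucleus accumbens short against no 0 to 2, nucleus accumbens long against short 0 to 2, amygdala long against no 1 to 0, ventral tegmental area long against no 21 to 10, ventral tegmental area short against no 6 to 1, the hypothalamic difference from the other 5 regions, long against short 1 to 2, lateral hypothalamus long against no gene lists 0 to 2, lateral hypothalamus short against no gene lists 0 to 4, lateral hypothalamus long against short gene lists 1 to 2, amygdala long against no gene lists 1 to 2, septum long against no gene lists 1 to 2, medial prefrontal cortex long against no gene lists 1 to 0. A filter at a mean of at least 200 moved mean of 6 regions long against short 2 to 1, the hypothalamic difference from the other 5 regions, long against short 1 to 7. No intensity trend moved septum short against no 14 to 8, septum long against short 15 to 5, ventral tegmental area long against no 21 to 8, ventral tegmental area short against no 6 to 3, ventral tegmental area long against short 19 to 7, the hypothalamic difference from the other 5 regions, long against short 1 to 2, lateral hypothalamus long against short gene lists 1 to 0. Array weights moved nucleus accumbens short against no 0 to 9, septum long against no 17 to 27, septum short against no 14 to 31, ventral tegmental area long against no 21 to 38, mean of 6 regions long against no 10 to 62, mean of 6 regions short against no 7 to 33, mean of 6 regions long against short 2 to 13, the hypothalamic difference from the other 5 regions, long against no 110 to 215, the hypothalamic difference from the other 5 regions, long against short 1 to 54, lateral hypothalamus long against no gene lists 0 to 1, amygdala long against no gene lists 1 to 3, medial prefrontal cortex long against no gene lists 1 to 0. No probe sets that can cross-hybridise moved lateral hypothalamus long against no 213 to 124, lateral hypothalamus short against no 161 to 87, lateral hypothalamus shared by long and short access 106 to 58, amygdala long against no 1 to 0, septum long against no 17 to 5, septum long against short 15 to 3, ventral tegmental area long against no 21 to 5, ventral tegmental area short against no 6 to 2, ventral tegmental area long against short 19 to 1, mean of 6 regions short against no 7 to 2, mean of 6 regions long against short 2 to 0, the hypothalamic difference from the other 5 regions, long against no 110 to 69, lateral hypothalamus above the other 5 27 to 16, nucleus accumbens above the other 5 84 to 41, amygdala above the other 5 32 to 14, septum above the other 5 42 to 25, ventral tegmental area above the other 5 69 to 36, medial prefrontal cortex above the other 5 60 to 31, lateral hypothalamus long against short gene lists 1 to 2, amygdala long against no gene lists 1 to 0. An estimated correlation in camera moved lateral hypothalamus long against short gene lists 1 to 0, amygdala long against no gene lists 1 to 0, septum long against no gene lists 1 to 0, medial prefrontal cortex long against no gene lists 1 to 0. Fry moved lateral hypothalamus long against no gene lists 0 to 7, lateral hypothalamus short against no gene lists 0 to 5, lateral hypothalamus long against short gene lists 1 to 3, septum long against no gene lists 1 to 5, medial prefrontal cortex long against no gene lists 1 to 0. All 63 arrays in 1 fit moved lateral hypothalamus long against no 213 to 116, lateral hypothalamus short against no 161 to 75, lateral hypothalamus long against short 64 to 15, nucleus accumbens short against no 0 to 2, nucleus accumbens long against short 0 to 1, amygdala long against no 1 to 2, septum long against no 17 to 0, septum short against no 14 to 0, septum long against short 15 to 0, ventral tegmental area long against no 21 to 0, ventral tegmental area short against no 6 to 0, ventral tegmental area long against short 19 to 0. Only the 2 groups compared moved nucleus accumbens short against no 0 to 1, septum long against short 15 to 9. Adjustment over all 18 contrasts moved lateral hypothalamus long against no 213 to 120, lateral hypothalamus short against no 161 to 87, lateral hypothalamus long against short 64 to 38, nucleus accumbens long against no 0 to 7, nucleus accumbens short against no 0 to 7, nucleus accumbens long against short 0 to 1, amygdala long against no 1 to 2. No medial prefrontal cortex arrays moved the hypothalamic difference from the other 5 regions, long against short 1 to 14. A 3-fold threshold moved lateral hypothalamus above the other 5 27 to 5, nucleus accumbens above the other 5 84 to 35, amygdala above the other 5 32 to 11, septum above the other 5 42 to 12, ventral tegmental area above the other 5 69 to 31, medial prefrontal cortex above the other 5 60 to 21. The spike-in level as a covariate, with median standard errors 1.52 to 3.46 times as large, moved lateral hypothalamus long against no 213 to 60, lateral hypothalamus short against no 161 to 66, ventral tegmental area long against no 21 to 0, ventral tegmental area short against no 6 to 0, ventral tegmental area long against short 19 to 0. The actin 3' to 5' ratio as a covariate moved lateral hypothalamus long against short 64 to 29. The 3 cortical arrays numbered 3 left out moved medial prefrontal cortex long against no gene lists 1 to 0. A 1.5-fold threshold as well moved lateral hypothalamus long against no 213 to 91, lateral hypothalamus short against no 161 to 66. Fewer samples, fewer probe sets or a larger family of tests account for part of these by construction. With single arrays left out, the ranges were nucleus accumbens short against no from 0 to 1 (main 0, 1 of 12), nucleus accumbens long against short from 0 to 1 (main 0, 1 of 12), mean of 6 regions long against no from 3 to 13 (main 10, 20 of 63), mean of 6 regions short against no from 3 to 20 (main 7, 7 of 63), mean of 6 regions long against short from 2 to 6 (main 2, 7 of 63), the hypothalamic difference from the other 5 regions, long against no from 71 to 144 (main 110, 1 of 63), the hypothalamic difference from the other 5 regions, long against short from 1 to 10 (main 1, 21 of 63), nucleus accumbens long against no gene lists from 0 to 1 (main 0, 1 of 12), amygdala long against no from 0 to 2 (main 1, 3 of 12), amygdala long against no gene lists from 0 to 3 (main 1, 4 of 12), lateral hypothalamus long against short from 31 to 64 (main 64, 5 of 12), lateral hypothalamus long against no gene lists from 0 to 1 (main 0, 3 of 12), lateral hypothalamus short against no gene lists from 0 to 1 (main 0, 2 of 12), lateral hypothalamus long against short gene lists from 0 to 3 (main 1, 5 of 12), septum long against no from 9 to 20 (main 17, 5 of 9), septum short against no from 7 to 15 (main 14, 4 of 9), septum long against short from 0 to 13 (main 15, 6 of 9), ventral tegmental area long against no from 8 to 25 (main 21, 4 of 9), ventral tegmental area short against no from 2 to 6 (main 6, 3 of 9), ventral tegmental area long against short from 8 to 19 (main 19, 3 of 9), medial prefrontal cortex long against no gene lists from 0 to 1 (main 1, 4 of 9). On each array 17.3% to 25.1% of probe sets were at the floor, and whether signal near background accounts for the rest was not tested.

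The replicate numbers were not taken to pair the arrays, because in no region did every pair of arrays with the same number deviate together at r over 0.1 (lowest r 0.029, -0.117, -0.18, 0.064, -0.039 and -0.001 in the order of the regions given first), although in the medial prefrontal cortex 8 of 9 pairs did, with a mean r of 0.486. In the septum 18 of 18 comparisons matched best with their own number, against 13, 11 and 8 of 24 and 12 and 12 of 18 elsewhere. In the medial prefrontal cortex array 3 also had the highest actin 3' to 5' ratio of each access group (1.93, 1.58 and 1.35, log2). The rule asks for every pair, which noise can defeat, and the design does not state a pairing. These values speak for arrays with the same number belonging together in the septum and medial prefrontal cortex, and leave it open elsewhere. The main fits, the exact permutation tests and the splits took the arrays as independent, so their results could change if the arrays are paired. A replicate block moved lateral hypothalamus long against short 64 to 103, nucleus accumbens long against short 0 to 1, amygdala long against no 1 to 0, septum long against no 17 to 29, septum short against no 14 to 22, ventral tegmental area long against no 21 to 47, ventral tegmental area short against no 6 to 10, ventral tegmental area long against short 19 to 33, mean of 6 regions long against no 10 to 3, the hypothalamic difference from the other 5 regions, long against short 1 to 7, lateral hypothalamus short against no gene lists 0 to 1, lateral hypothalamus long against short gene lists 1 to 0, amygdala long against no gene lists 1 to 0.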

Other observations

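Across 858 probe sets, which are not independent replicates, the differences between long and no access correlated at most at 0.192 (septum and nucleus accumbens), and those of the lateral hypothalamus correlated at 0.166 with the nucleus accumbens, -0.109 with the septum and 0.0619 with the ventral tegmental area. Noise lowers such values, and what equal differences in every region would give was not computed. The hypothalamic values rest on the no access arrays that stand apart in their controls. Igf2, a growth factor made by choroid plexus and meninges, was lower by -1.49 in the amygdala and by -1.14 in the septum and higher by 0.59 in the ventral tegmental area, each past the threshold in its own fit, though in the ventral tegmental area, where the spike-in and antisense controls were also higher with access, it was 0.35 ± 0.25 with the spike-in level as a covariate, a setting chosen after the data were seen (limma, adjusted p = 0.695). The septal value came from a different probe set of the gene than the other 2 values, the other probe sets did not pass there, 2 of the 3 others went the opposite way in the ventral tegmental area, and whether these effects differ from each other was not tested.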
